A study of Mus musculus with 6 samples.

How the data were processed

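RNA from sorted aortic macrophages of 3 naive and 3 sepsis samples was hybridised to 1 microarray each, with 18 to 20 aortas pooled per sample, per the labels. RNA was isolated with a kit for small samples and labelled with biotin, per the labels' protocols. The deposited table holds log2 values for 35556 probe sets on 6 arrays with no missing value. The submitters' processing notes name RMA and the package oligo, with no version given in the sources used here. RMA subtracts background, makes the arrays' probe distributions alike by quantile normalization and summarises probes into probe sets on the log2 scale, so it removes any shift shared by all genes and compresses differences between dim genes. The medians of the deposited arrays lay between 6.51 and 6.57, and their interquartile ranges between 2.58 and 2.69 except on Sepsis 3, at 2.39. The treatment text of the labels also mentions an injection of LPS; no sample is labelled with it, and the samples were grouped by their titles as naive or sepsis.

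Probe sets were named with the platform annotation. Of the 35556 probe sets, 21789 had 1 gene symbol, 1621 had several and 12146 were unnamed here, and 21698 of the first were found in the RefSeq gene table by their gene identifier, all with the same symbol. For each of 19938 genes the probe set with 1 symbol and the highest mean over all arrays was used, and 999 genes had more than 1. No further normalization and no filter on dim genes was applied.

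Sepsis was compared with naive over all 6 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, without trend or robust options), 2-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The same fit was run on all probe sets. Gene lists, 33 of pathways and 16 of cell types other than the sorted one, were tested with camera at a preset correlation of 0.01, beside camera with an estimated correlation and fry. They held 999 symbols, of which 901 were measured. An adjustment over the list alone used the members' p-values only. Sort markers and list means per array were also compared by exact permutation of the arrays. The smallest p this allows is 0.1. Principal components and correlations were taken over all genes. Plots were drawn with matplotlib 3.10.9.

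The samples, groups, tests, lists and most alternative settings were fixed before the data were examined. The genes named are, in each direction, up to 12 with the largest difference among those that passed without overlap, filled up to 6 with the smallest p where fewer passed, without predicted, non-coding and receptor-family symbols; the 5 sort markers; for each list that passed and for 7 lists chosen in advance, the 4 members with the smallest p in the direction of the list's median and the 2 with the highest level; and, in other lists, members that passed.

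The test was checked on simulated data for 19938 genes, with independent normal noise at each gene's SD as limma estimated it on these arrays. It recovered 53.4% of 1.5-fold, 98.7% of 2-fold and 100% of 4-fold changes, and 6.22% of its calls were false. Each simulation held 201 changed genes, where 2 passed on the real arrays, and the adjustment is stricter when fewer genes change. These shares therefore do not carry over to the real arrays, where Fcgr4, at 2.135-fold, did not pass. With independent noise, camera found a list shifted by −0.3 in 10 of 10 simulations and called 0 other lists. The arrays' real noise is shared between genes, which this simulation leaves out.

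Alternatives left out each array in turn, used the replicate number as a block, centred arrays on the median, applied cyclic loess, left out the dimmest 30% or 50% of genes, used trend and robust options, array weights or the mean of a gene's probe sets, and changed the threshold, the test and the genes included. Probe sets with several symbols entered only the fit over all probe sets. No scanner files were used here.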

Results

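Gene expression was measured in macrophages from the aortas of naive mice and of other mice 7 days after sepsis was induced by puncture of the cecum, which lets gut contents into the abdominal cavity. The cells were sorted from male C57/B6 mice aged 6 to 8 weeks as CD45-positive cells with high CD11b and F4/80 that also carried MerTK and CD64, and 18 to 20 aortas were pooled for each sample. There were 3 naive and 3 sepsis samples, given as biological replicates, each on 1 microarray. The values were deposited on a log2 scale, and 19938 named genes were compared. The number of arrays limits the precision: the median 95% confidence interval of a gene's difference reached 0.28 log2 to either side, a 1.22-fold change.

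The genes of the sort gate were read first. Adgre1 (F4/80), Ptprc (CD45), Itgam (CD11b), Fcgr1 (CD64) and Mertk lay at or above the 96.0th percentile of all genes by level. Their sepsis minus naive differences were 0.10 for Adgre1, 0.080 for Ptprc, 0.10 for Itgam, 0.15 for Fcgr1 and 0.097 for Mertk, on the log2 scale. None passed the limma test with Benjamini-Hochberg adjustment (adjusted p = 0.999 for each), and 2-sided exact permutation p ranged from 0.2 to 0.4, where 3 against 3 arrays cannot go below 0.1. As a list, these 5 genes had a mean difference of 0.11 and a camera adjusted p of 0.0555 (adjusted p = 0.962 with an estimated correlation). The list passed as higher with trend and robust options (camera adjusted p = 0.00761), without the dimmest 30% or 50% of genes (0.0283 and 0.0314), without Naive 3 (0.0418), with median centring (0.044) and with cyclic loess (0.0479), while without Sepsis 2 its mean was 0.056 (0.261).

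The comparison of sepsis with naive asks which genes differ in aortic macrophages a week after the puncture. No group had the surgery without the puncture. In all that follows, effects of the surgery and of the infection therefore cannot be told apart. Saa3, an acute-phase serum amyloid A protein that macrophages can make, rose 11.2-fold (95% confidence interval 7.46 to 16.9), from 5.88 ± 0.21 in naive to 9.37 ± 0.58 in sepsis arrays (log2, SD, n = 3 each; limma adjusted p = 0.00822). Cd55, a membrane protein that limits complement activation on the cell's own surface, rose 5.41-fold (3.77 to 7.79), from 5.86 ± 0.33 to 8.29 ± 0.43 (log2, SD, n = 3 each; limma adjusted p = 0.0294). All 3 sepsis arrays lay above all 3 naive arrays for both genes. Their naive levels lay among those of the 1190 olfactory and vomeronasal receptor genes, silent in most tissues, of which 85.1% were lower than Saa3 and 84.7% lower than Cd55, so both folds are understated to the extent that the naive signal is background. They were the only genes of the 19938 to pass, and no gene passed in the other direction. With the replicate number as a block Cd55 did not pass (limma adjusted p = 0.056), its log2 difference being 2.44 as before.

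The next genes by p did not pass after adjustment, though their arrays did not overlap between the groups. Among those higher after sepsis, Cxcl13, a chemokine that attracts B cells, had a log2 difference of 2.97 ± 0.40 (SE; limma adjusted p = 0.187), from 7.34 to 10.31, and passed with the replicate number as a block (limma adjusted p = 0.00645). Fcgr4, an activating receptor for IgG, had 1.09 ± 0.12 (limma adjusted p = 0.0796). Slc13a3, a carrier of dicarboxylates, had 0.93, and Plbd1, a phospholipase B-like protein, 0.79. Among those lower after sepsis, none of which passed, Prc1, which bundles microtubules of the mitotic spindle, had −0.83, Retnla, a secreted protein of alternatively activated macrophages, −0.83, and Mmp13, a collagenase, −0.78. Lsp1, an actin-binding protein of leukocytes, had −0.62, Qpct, a glutaminyl cyclase, −0.62, and Adgre4, an adhesion receptor of myeloid cells, −0.46. At an unadjusted p under 0.05 there were 565 genes, 231 higher and 334 lower, where about 997 would be reached by chance among independent genes. The groups did not overlap for 7.27% of genes, against 10% by chance. A fit over all 35556 probe sets, named or not, called 0 with limma, and 1091 had an unadjusted p under 0.05. Leaving out Naive 1, 2 or 3 or Sepsis 1 left 0 genes past the threshold, and leaving out Sepsis 2 left 1, Saa3. Array quality weights called 442 genes in a fit of the weights that did not converge, and 5 with weights estimated gene by gene, a setting chosen after seeing the data.

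**Figure D1:**
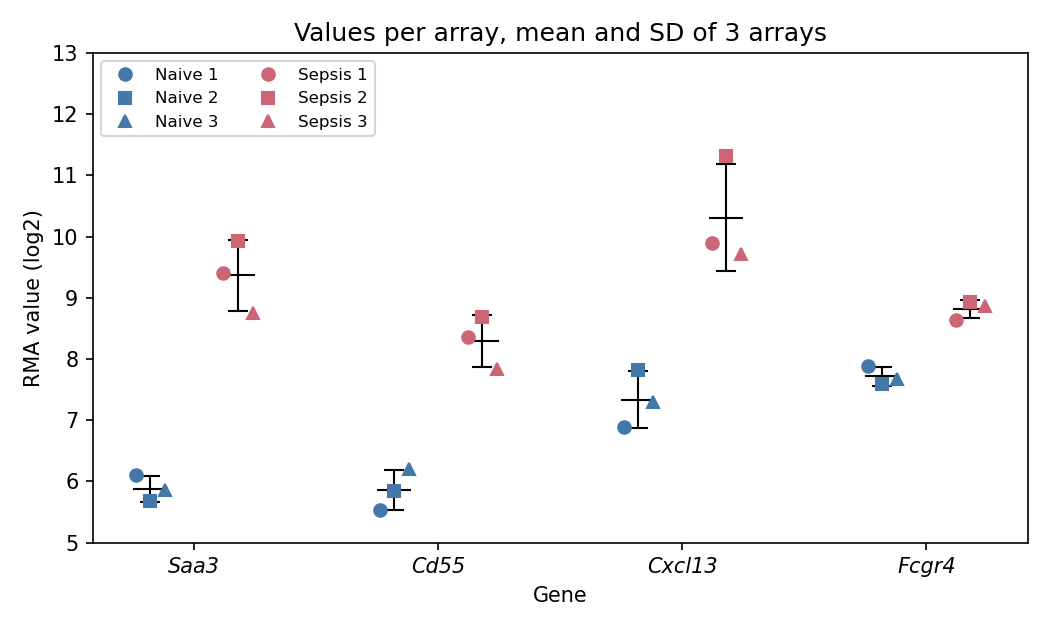
Deposited RMA values (log2, vertical axis) of 4 genes on each of the 6 arrays, naive in blue and sepsis in red, with bars for the mean and SD of 3 arrays. Saa3 rose from a mean of 5.88 to 9.37 and Cd55 from 5.86 to 8.29, while the differences of Cxcl13 (2.97) and Fcgr4 (1.09) did not pass the adjusted test.

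Of 49 gene lists fixed before the data were examined, 7 passed camera with its preset correlation of 0.01, 5 of them lower and 2 higher after sepsis. None of the 7 held when the correlation between genes was estimated from these arrays (adjusted p = 0.962 with an estimated correlation for each), and the directional fry test called 0 lists. At an unadjusted camera p under 0.05 there were 14 lists.

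Genes of the cell cycle's G2 and mitotic phases fell as a list: 31 of 31 measured members had a lower mean after sepsis, with a median log2 difference of −0.31 (camera adjusted p = 3.08e-19; adjusted p = 0.962 with an estimated correlation, which was 0.48 among these genes). No member passed over all genes, and 6 passed adjusted over the list alone. Top2a, the topoisomerase that untangles DNA before division, had −0.54 ± 0.15 (SE), Prc1 −0.83 ± 0.17, Knl1, of the kinetochore, −0.49 ± 0.13 and Cenpe, a kinetochore motor, −0.46 ± 0.13. Kif23, a motor of cytokinesis at a higher level than most of the list, had −0.40 ± 0.16. The list means of the sepsis arrays were 7.15, 6.93 and 6.82 and those of the naive arrays 7.30, 7.15 and 7.44 (log2; 2-sided exact permutation p = 0.1, the smallest possible here). The mean difference was −0.33, and −0.12 with array weights and −0.18 with weights estimated gene by gene (camera adjusted p = 0.00548 and 7.69e-07).

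Genes of DNA replication and S phase fell as a list too, with 29 of 31 members lower and a median of −0.15 (camera adjusted p = 1.15e-05; adjusted p = 0.962 with an estimated correlation). No member passed over all genes or adjusted over the list alone. Uhrf1, which keeps DNA methylation through replication, had −0.54, Tyms, which makes thymidylate, −0.40, Pole, a replicative polymerase, −0.33 and Ccne2, cyclin E2, −0.28. Pcna, the sliding clamp of the polymerases, and Rfc5, of the clamp loader, had −0.17 and −0.34. Sepsis 3 lay lowest, with a list mean of 7.00 against 7.36 and 7.33 in the other sepsis arrays and 7.35 to 7.44 in the naive arrays, and without it the mean difference was −0.050 and the call was lost (camera adjusted p = 0.079). It was also lost with array weights (mean −0.038; 0.367) and with weights estimated gene by gene (mean −0.060; 0.109), and the receptor-gene covariate, chosen after seeing the data, left it passing with a mean of −0.089 against −0.16 (0.00234).

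Immediate early and dissociation-associated genes, which tissue digestion also induces, fell as a list, 27 of 28 members being lower with a median of −0.19 (camera adjusted p = 3.13e-10; adjusted p = 0.962 with an estimated correlation). No member passed over all genes or adjusted over the list alone. Gadd45b, a stress-induced gene, had −0.65, the early gene Ier2 −0.51, and the heat shock genes Hsph1 and Hspa1a −0.38 and −0.36. Dusp1, a phosphatase of MAP kinases, had −0.11, and the constitutive chaperone Hspa8 had 0.0058. Each sepsis array's list mean lay below each naive array's (9.92 to 10.10 against 10.13 to 10.39; 2-sided exact permutation p = 0.1). The groups did not overlap for 6 of the 49 lists, 2 lower and 4 higher after sepsis, against 10% by chance.

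Cholesterol biosynthesis genes fell as a list, 15 of 20 members being lower with a median of −0.12 (camera adjusted p = 0.00623; adjusted p = 0.962 with an estimated correlation). No member passed over all genes or adjusted over the list alone. Idi1, an isoprenoid isomerase, had −0.68, Insig1, a sterol-regulated brake on the pathway, −0.43, Sqle, squalene epoxidase, −0.36, the sterol carrier Stard4 −0.33 and Srebf2, the pathway's main transcription factor, −0.24. The call was lost without Sepsis 3 (mean −0.050; camera adjusted p = 0.158) and without Naive 2 (mean −0.094; camera adjusted p = 0.214). It was also lost without the dimmest 50% of genes (mean −0.14; 0.0543), with array weights (mean −0.13; 0.0687) and with the median level of the receptor genes on each array as covariate, chosen after seeing the data (mean −0.081; 0.0661).

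The 2 lists called higher each rested on few members. Of 9 Fc receptor genes, 6 were higher, with a median of 0.12 (camera adjusted p = 0.00745; adjusted p = 0.962 with an estimated correlation). Fcgr4 was the 1 member that passed adjusted over the list alone and none passed over all genes. Trim21, a cytosolic antibody receptor, had 0.21, Fcgr1 0.15, Fcgr3 0.12 and the shared signalling chain Fcer1g 0.058. Of 21 complement genes, 13 were higher, with a median of 0.023 and a mean of 0.17 (camera adjusted p = 0.0258; adjusted p = 0.962 with an estimated correlation). Cd55 passed over all genes, and Cd55 and Cfb, complement factor B, passed adjusted over the list alone, Cfb with 0.55 ± 0.11 (SE). Serping1, the C1 inhibitor, had 0.58, the dim C1s1 0.38, and the abundant C1q chains C1qa and C1qc 0.023 and 0.062. Without Sepsis 3 both calls were lost while the mean differences stayed, at 0.16 for Fc receptors (0.18 with all arrays; camera adjusted p = 0.186) and 0.21 for complement (camera adjusted p = 0.1). The complement call was also lost without Naive 1 (mean 0.13; 0.103), without Sepsis 2 (mean 0.12; 0.175) and with the replicate block (mean 0.17; 0.0851). Both calls were lost with array weights (means 0.14 and 0.14; 0.337 and 0.402), with weights estimated gene by gene (0.15 and 0.16; 0.133 and 0.225) and with the receptor-gene covariate (0.16 and 0.19; 0.127 and 0.0736).

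Markers of smooth muscle cells and pericytes, a check for other cells of the aortic wall, were called lower, with 20 of 21 members lower and a median of −0.28 (camera adjusted p = 0.000645; adjusted p = 0.962 with an estimated correlation). None passed over all genes or adjusted over the list alone. The contractile genes Acta2, Tagln and Tpm2 had −0.78, −0.56 and −0.60, the pericyte gene Rgs5 −0.67 and the muscle filament gene Des −0.37. Over the alternatives the dim Des stayed between −0.47 and −0.33. The others rose as far as 0.33 (Acta2), −0.089 (Tagln), −0.17 (Tpm2) and −0.089 (Rgs5). Naive 2 set the list's mean difference: the list mean on that array was 7.56 against 6.42 to 6.53 on the other 5 arrays. Without it the mean difference turned to 0.034 (camera adjusted p = 0.523). The call was also lost without Sepsis 2, where the mean stayed at −0.33 (camera adjusted p = 0.0653). Fibroblast markers were highest on the same array, at 7.78 against 7.09 to 7.37. No other of the 16 cell type lists passed camera, and mixed fry, which counts changes in both directions, called the mesothelial and peritoneal macrophage markers (adjusted p = 0.00122), a list that holds Saa3.

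**Figure D2:**
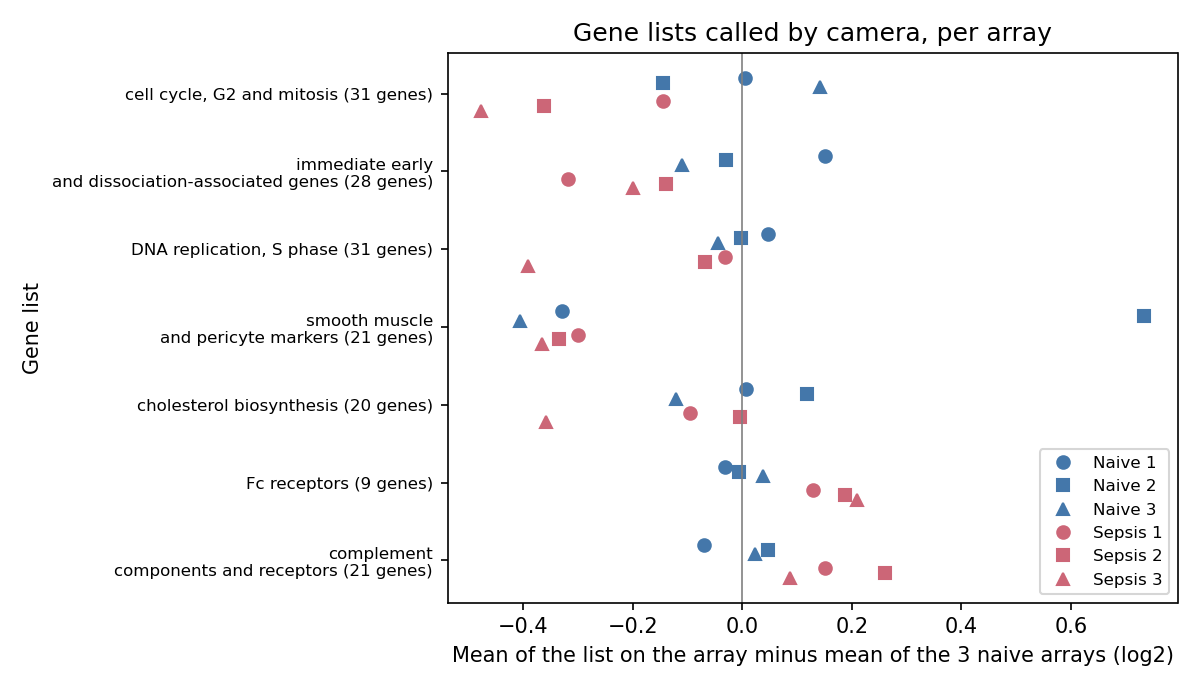
Mean of each list's genes on each array minus the mean of the 3 naive arrays (log2, horizontal axis) for the 7 lists called by camera, naive in blue and sepsis in red. The 3 sepsis arrays lie below the naive arrays for G2 and mitosis, where Sepsis 1 and Naive 2 nearly coincide, and for immediate early genes, while Naive 2 stands alone among smooth muscle markers with a list mean of 7.56.

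Lists for macrophage identity and inflammation did not pass. Of 29 genes of resident arterial and tissue macrophages, 10 were higher and 19 lower, with a median of −0.027 (camera adjusted p = 0.546). The abundant members Mrc1, the mannose receptor, Cbr2 and Lyve1, the hyaluronan receptor of resident arterial macrophages, had 0.010, −0.10 and −0.15, and Timd4, a phosphatidylserine receptor of long-lived macrophages, Fcna and Vsig4 had −0.37, −0.46 and −0.31. Interferon-stimulated genes divided evenly, 16 higher and 16 lower (camera adjusted p = 0.567, and 0.962 with an estimated correlation). Members named by rule, from the higher side or for their level, had 0.62 (Cxcl9), 0.47 (Iigp1), 0.23 (Ifih1), 0.15 (Gbp7), 0.043 (Rtp4) and 0.014 (Parp14). This list passed as higher without Naive 1 (mean 0.093; camera adjusted p = 0.0122), with array weights (mean 0.13; 0.00548) and with weights estimated gene by gene (mean 0.095; 0.0431), and had a mean of −0.067 without Naive 2. Of the MHC class II genes, 7 were higher and 5 lower, with a median of 0.0086 (camera adjusted p = 0.567). Those named by the same rule had 0.18 (H2-Aa), 0.12 (H2-Ab1), 0.091 (H2-DMa), 0.081 (H2-Eb1) and 0.013 (Ctss).

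Of 29 inflammatory cytokines and chemokines, 18 were lower and 11 higher (median −0.072; camera adjusted p = 0.0812; adjusted p = 0.962 with an estimated correlation), and the list passed as lower without Naive 2, Naive 3 or Sepsis 3 (camera adjusted p = 0.0113, 0.0364 and 0.0436), while without Naive 1 its mean was −0.013 against −0.094 (0.591). Tnf had −0.47, Tnfsf9 −0.77, Ccl24 −0.44, Cxcl2 −0.33 and the abundant Ccl2 −0.017, none of them past the test. The chemokine Cxcl13, with 2.97, was not on this list, so the list's values leave it out. Of 22 monocyte markers, 10 were higher and 12 lower, with a median of −0.021 (camera adjusted p = 0.96), with −0.46 for S100a4, −0.49 for Vcan, −0.38 for S100a6, −0.31 for Nr4a1 and 0.013 for Lyz2. Ms4a4c, a membrane protein of the CD20 family named after its values were seen, was the 1 monocyte marker that passed adjusted over the list alone, with 0.54. At an unadjusted limma p under 0.05, 4 monocyte markers were lower and 2 higher, Ms4a4c and Ccr2 (0.38), a chemokine receptor also named after its values were seen. Neutrophil markers had a median of 0.015 (camera adjusted p = 0.0636), with 0.40 for Csf3r, the receptor for G-CSF, 0.24 for Mmp9, and 0.25, 0.17 and 0.26 for the dim Padi4, Lcn2 and Ly6g. None of these genes passed over all genes.

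The groups overlapped on the first principal component and did not overlap on the second, which held 15.9% of the variance. On the second, Naive 2, Naive 3 and Sepsis 3 lay close together, with scores of 1.62, 2.06 and 0.44. Naive 1 lay at 17.9 and Sepsis 1 and 2 at −10.4 and −11.6. No test was made, and 3 against 3 arrays fail to overlap on a given axis in 10% of cases by chance. Sepsis 3 stood apart on the first principal component, with a score of 36.1 against −15.5 to 5.46 for the other 5 arrays, and that component held 51.3% of the variance. Its mean correlation with the other arrays over genes was 0.982, where the lowest mean of any other array was 0.989. The difference between the groups held 17.4% of the sum of squares, against 20% with no effect, and another split of the arrays held 30.5%.

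**Figure D3:**
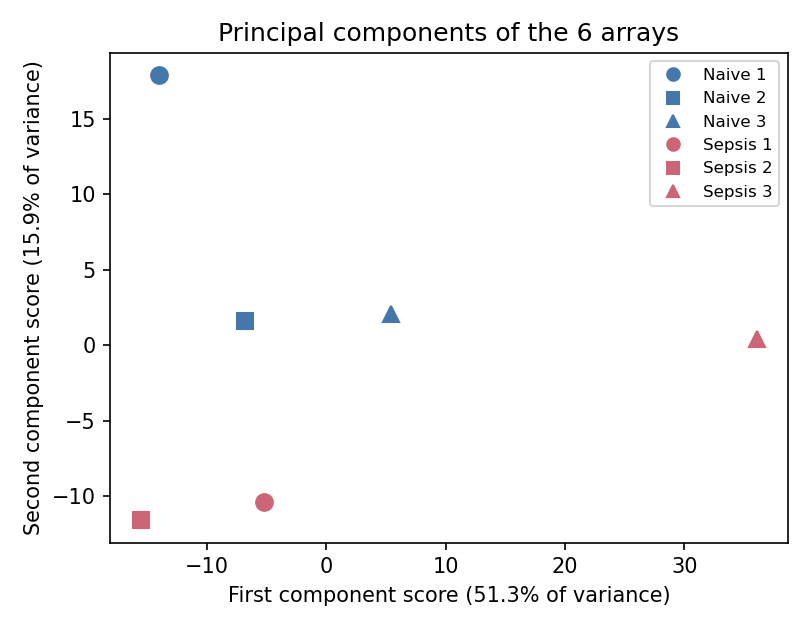
Scores of the 6 arrays on the first (horizontal) and second (vertical) principal component over 19938 genes, in arbitrary units, naive in blue and sepsis in red. Sepsis 3 lies alone at 36.1 on the first component, and the other arrays of both groups lie between −15.5 and 5.46.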

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

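Settings with the receptor-gene covariate and with array weights estimated gene by gene were chosen after seeing the data. The 2 genes that passed remained Saa3 and Cd55 with median centring, cyclic loess, the mean of probe sets per gene, fold limits, protein-coding genes only and the covariate, and 3 genes passed without the dimmest 30% of genes (with Fcgr4) and with trend and robust options (with Gm6377). Leaving out 1 array gave 0 to 2 genes: 0 without Naive 1, 2 or 3 or Sepsis 1, 1 without Sepsis 2 (Saa3) and both without Sepsis 3. The differences themselves kept their direction, from 3.21 to 3.79 for Saa3 (adjusted p from 2.56e-06 to 0.0732) and 2.24 to 2.67 for Cd55 (2.42e-05 to 0.217) over 12 alternatives, so the calls changed and the directions did not. Without the dimmest 50% of genes 5 passed (Saa3, Cd55, Fcgr4, Cxcl13 and Gm6377, a predicted gene named after its values were seen), where fewer genes were tested, and the ordinary t statistic called 0. Array weights called 442 genes, 240 higher and 202 lower, but the fit of the weights stopped without converging and gave Sepsis 1 a weight of 10.7 against 0.182 for Sepsis 3. Weights estimated gene by gene called 5. The fit over all probe sets called 0 in each of its alternatives.

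Whether the replicate number pairs the samples stays open. Deviations of same-numbered arrays correlated at 0.17, 0.08 and 0.36 over genes, and 4 of the 6 arrays correlated best with their own number. Arrays with different numbers correlated at −0.34 (Naive 3 with Sepsis 2) to 0.25 (Naive 1 with Sepsis 2). With the replicate block, 2 genes passed, Cxcl13 and Saa3, 1 of them shared with the fit without it, and 6 lists passed, complement being lost; Cd55 (2.44 in either fit) did not pass.

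Of 49 lists, 7 passed, and leaving out 1 array gave 5 (without Sepsis 2) to 14 (without Naive 3). Trend and robust options gave 11, the covariate 4, camera with an estimated correlation 0, directional fry 0 and mixed fry 3 (complement, Fc receptors, and mesothelial and peritoneal macrophage markers, which hold Saa3); the cause of these shifts was not tested. G2 and mitosis and immediate early genes passed in each setting with the preset correlation, but the mean difference of G2 and mitosis moved from −0.33 to −0.12 with array weights and −0.18 gene by gene. Smooth muscle markers ranged from −0.54 without Naive 3 to 0.034 without Naive 2 in mean difference. Lists that did not pass with all arrays changed sign when 1 array was left out: resident macrophage genes (−0.13 to 0.022), interferon-stimulated genes (−0.067 to 0.093, where the upper value passed, as did 0.13 with array weights), MHC class II (−0.019 to 0.041) and monocyte markers (−0.058 to 0.012).

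Of 996 values of the 83 genes named by rule under alternatives, 932 kept direction and side of the threshold, 27 came to pass, 24 of them with array weights, 10 (of Saa3 and Cd55) ceased to pass and 27 changed sign. Those belonged to 11 genes, none past the threshold with all arrays or in the changed value; the cause was not tested. With array weights the values were −0.031 for Mertk, 0.050 for Rfc5, −0.064 for Ctss, −0.039 for C1qa and −0.0078 for Hspa8, and gene by gene −0.037 for Ctss and −0.0097 for C1qa. With cyclic loess they were −0.0030 for Mrc1, −0.0081 for Hspa8 and −0.0016 for Lyz2, and with the covariate −0.00096 for Hspa8. Leaving out 1 array gave −0.13 to 0.15 for Rtp4, −0.045 to 0.074 for Parp14, −0.014 to 0.048 for Ctss, −0.10 to 0.055 for Ccl2, −0.027 to 0.054 for C1qa, −0.033 to 0.031 for Hspa8, −0.028 to 0.059 for Lyz2 and −1.38 to 0.33 for Acta2. Signal near background limits dim genes: the 1190 olfactory and vomeronasal receptor genes, silent in most tissues, had medians of 4.73 to 5.13, so differences among genes at that level are compressed.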

Other observations

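The tests on Sepsis 3, the test of what the cell cycle list keeps without it and the level that markers had to exceed were chosen after those results were seen. The others in this part were chosen before their own results were seen, but some address patterns already found on these arrays. Among lists the report does not describe, alternative activation genes had 12 of 20 members lower and a median of −0.064 (camera adjusted p = 0.12). Retnla and Mgl2, a galactose-binding lectin named after its values were seen, passed adjusted over the list alone, with −0.83 and −0.55, and none passed over all genes. Genes of the unfolded protein response had 19 of 23 members lower with a median of −0.075 (camera adjusted p = 0.0555), and genes of matrix remodelling 15 of 22 lower with a median of −0.11 (camera adjusted p = 0.0591), so neither passed.

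Saa3, Cd55 and Cxcl13 were higher on each sepsis array than on any naive array, Cxcl13 without passing the adjusted test. Mesothelial cells or macrophages of the inflamed peritoneum carried into the sort are candidate sources. The 5 mesothelial markers Msln, Upk3b, Lrrn4, Wt1 and Krt19 lay between the 12.7th and 35.4th percentile of genes by level. They differed by −0.061 in mean, with an upper 95% limit of 0.22. Whether the gate on CD45, MerTK and CD64 removed such cells was not tested. The smooth muscle gene Acta2 reached 10.86 on Naive 2 despite the gate, against 7.44 to 8.12 on the other arrays. The 9 peritoneal macrophage markers, of which Fcna was abundant in naive cells, differed by −0.054 with an upper limit of 0.12. Fcna, also on the list of resident macrophage genes, lowered this mean, with −0.46 against −0.19 (Ltbp1) to 0.21 (Serpinb2) for the others. Neither set rose by the 0.5 fixed for carry-over before that test was run, but that bound was too weak. Of the markers, 0 of 5 and 3 of 9 lay above 6.48, the 95th percentile of receptor genes silent in most tissues. A small share of such cells therefore stays open. Sepsis 3 was the lowest sepsis array for each of the 3 genes, which argues against that array as the source of their differences. Leaving it out could therefore only raise them, to at least 109%. A response of the aortic cells to sepsis is 1 hypothesis beside carry-over, found on these arrays and not itself tested. Values from pooled cells do not separate a change within the cells from a change in the mix of cells sorted. Of the 10 splits of the 6 arrays, 1, the real one, gave 2 genes and the highest other gave 0, and 10 splits are too few for a share under 0.05.

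The G2 and mitosis list was lower after sepsis, with a mean difference of −0.33. None of 10000 random lists of the same levels, 0%, had a median as low, and their lowest was −0.14, which argues against a loss shared by genes of that level. Random lists were not matched on the correlation among the members, estimated at 0.48, so they bear on level alone. For the same reason a count of members is not a count of independent genes. Without Sepsis 3 the list kept 77.3% of its difference, −0.25 (camera adjusted p = 2.27e-13), with 31 of 31 members lower and a median of −0.25 against −0.074 for the lowest random list. Against this, the 95% confidence interval of −0.68 to 0.17 over arrays does not rule out that the array carries most of it, and Sepsis 1 lay only 0.00087 below the lowest naive array. Of the 10 splits, 1, the real one, gave a mean as large, and the highest other gave 0.3285 in size against −0.3291; for the number of lists passing camera, 3 splits reached the 7 of the real one and the highest gave 12, and in either case 10 splits are too few for a share under 0.05. Fewer dividing macrophages a week after sepsis may be 1 reading, but Sepsis 3 and variation between pools remain open.

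Sepsis 3 stood apart from the other 5 arrays. Its receptor genes, silent in most tissues, had a median 0.35 above the mean of the others, and its 1000 brightest genes a median 0.12 lower (−0.12), as low contrast between silent and bright genes would give; both medians had been seen when this test was chosen, so it cannot bear the explanation out. The highest median shift among 16 cell type lists was 0.19, for NK cell and innate lymphoid markers, below that of the receptor genes, but only 105 of the 269 markers lay above 6.48. The 4 lists with at least 50% of their markers above it did not rise (−0.080 for monocyte, −0.22 for endothelial, −0.17 for fibroblast and −0.14 for platelet markers), and cell types with dim markers stay open. The values on a stronger response are mixed: 0 of Saa3, Cd55, Fcgr4 and Cxcl13 were highest on this array, 3 were the lowest of the sepsis arrays, and Sepsis 1 and 2 lay at −5.23 and −15.5 on the first component, away from the 36.1 of Sepsis 3, but of the 7 lists called by camera 5 had Sepsis 3 furthest from the naive mean in the list's direction, G2 and mitosis at −0.48 against −0.15 and −0.36. Those 7 lists were called with Sepsis 3 included, which favours lists where it lies far out, so this count cannot bear the explanation out. A stronger response in that pool is not excluded. Without Sepsis 3, 1161 genes had an unadjusted p under 0.05 against 565 with it. About 997 would be reached by chance among independent genes. The split of Naive 1, Naive 2 and Sepsis 2 against the rest gave the most of all splits, 2283, with 0 past the adjusted threshold. The other splits that mix the groups gave 226 to 2095. The split with 2283 was picked as the highest, and it sets the arrays lowest on the first component against a side that holds Sepsis 3. It therefore cannot tell a structure of the arrays other than the groups from the distance of Sepsis 3.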
